A study of Homo sapiens with 6 samples.

How the data were processed

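RNA was measured by bulk sequencing in 6 libraries of SNU-668, an established human gastric cancer cell line, described in the labels as resistant to erastin. Erastin is a small molecule that blocks cystine import through the SLC7A11/SLC3A2 antiporter and so induces ferroptosis, a form of cell death driven by lipid peroxidation. Per the labels' protocols, the resistant cells were kept in DMEM with 10% fetal bovine serum and received either a control shRNA or an shRNA against ALKBH3. RNA was extracted with Trizol, 1 ug of total RNA was enriched with oligo dT, and libraries were made with a strand-specific dUTP kit and sequenced in paired 150-cycle reads. The sample titles begin with the code RLS3, which the labels do not explain, so the resistance of the cells is stated only as the protocols give it. The groups were taken from the genotype label, which reads ALKBH3 knockdown for 3 libraries and WT for the other 3. That the latter received a control shRNA comes from the treatment protocol and the series design. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

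The deposited table holds raw read counts per gene and library, per the file headers, with a further set of columns that the header describes as counts normalised by DESeq2. The raw count divided by the normalised count was a single factor in each library, from 0.903 to 1.15, so those columns are raw counts over 1 size factor per library. The submitters' processing notes list fastp 0.20.0, STAR 2.7.9a, featureCounts 2.0, DESeq2 without a version and the build hg19. The settings of these tools, the annotation release and whether counting used the strand of the reads are not given in the sources used here. Reads of near-identical gene copies and of antisense neighbours can therefore be divided in an unknown way. The table lists 20325 protein-coding genes by Ensembl identifier, 4008 of them with 0 reads in all 6 libraries. A further 2 lines held no values and were not analysed here. Symbols were taken from the table, and genes were matched by identifier because 81 symbols belong to more than 1 gene.

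Library totals were 14244932, 15470321 and 14983057 counts in the control libraries and 17880183, 17582198 and 14890452 in the knockdown libraries. Genes with too few counts were removed with edgeR's filterByExpr, which left 12305 genes. The genes removed hold 0.056% of all counts. Counts were scaled with edgeR's TMM factors, from 0.987 to 1.01, and levels are given as CPM of the scaled library size, with the SD over the 3 libraries of a group. The groups were compared with edgeR 4.0.16 in R 4.3.3, by glmQLFit with robust dispersion and glmQLFTest on a design with the group alone. P-values were adjusted over the 12305 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are knockdown over control. Their SE was derived as the absolute log2 fold change over the square root of the test's F statistic.

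There were 42 gene lists, fixed before the data were examined, as were the comparison, its design and the settings tried against it. They cover ferroptosis, stress responses, metabolism, proliferation, RNA methylation, inflammation, cell identity, other cell types and the neighbours of ALKBH3 on its chromosome. Each list was tested with limma 3.58.1 camera on voom values with a preset correlation between genes of 0.01, two-sided, with adjustment over the 42 lists. The test was repeated with an estimated correlation and with fry, whose directional test asks whether the genes of a list move on balance 1 way and whose mixed test asks whether they change in either direction. Neither fry test compares a list with other genes. Called members were counted from the edgeR fit, once with p adjusted over all 12305 genes and once with p adjusted over the list alone.

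The genes named in the text follow a rule that was also fixed in advance. They are ALKBH3; SLC7A11, GPX4, ACSL4, AIFM2, TFRC and HMOX1 whatever their result; the 8 called genes with the highest and the 8 with the lowest fold change among those with a mean of at least 5 CPM and no overlap between the groups; and up to 3 called members of each list with the smallest adjusted p. This gave 93 genes, 89 of them called. The results of 1 list and of some single genes are not reported here. Other genes are named only where the text says that they were chosen after their values were seen.

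The alternatives were other scalings (DESeq2's size factors within edgeR, and library totals alone), no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited normalised count plus a pseudocount of 1, dispersion without robust estimation, the replicate number as a block, stricter thresholds, and a fit without each library in turn. The same code was tested on simulated data drawn from the means and totals of these libraries, with 200 of the 12305 genes and, besides these, the members of 1 list changed. For this comparison of 3 with 3, edgeR recovered 85% of the genes planted at 1.5-fold and 90% of those at 2-fold, and 10 of its 220 calls, which include members of that list, were false. In the same simulation, camera found the list planted with a shift of 0.5 on the log2 scale and no other. Genes were drawn there independently of each other. In the real libraries the estimated correlation was 0.11 for ATF4 and integrated stress response, 0.4 for hypoxia and glycolysis and 0.54 for heat shock proteins. The simulation therefore cannot show how often camera calls a list of correlated genes falsely.

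For transcript sequence, GC content and length, genes were matched by identifier to a GENCODE annotation of the GRCh38 build. No coordinate from that build is given, and all coordinates in the text are those of the deposited table on hg19. Terms of the table's own gene annotation were tested with a hypergeometric test over tested genes with a usable annotation of that kind, for terms of 10 to 500 genes. The background held 9016 genes for biological process terms and 5068 for pathways. A further 762 and 15 tested genes, whose entry was not available, were left out of it and of the term sizes. The test takes genes as independent of each other. The figures were drawn with Python 3.11.15 and Matplotlib 3.10.9.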

Results

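The transcriptome of SNU-668 gastric cancer cells, described in the labels as erastin-resistant, was profiled after transfer of an shRNA against ALKBH3 or of a control shRNA, in 3 libraries each. ALKBH3 is a dioxygenase that removes methyl groups from alkylated DNA and RNA, among them the 1-methyladenosine mark of RNA (m1A). The design asks which transcripts differ when ALKBH3 is reduced in cells that have become resistant to a ferroptosis inducer. Library totals ran from 14244932 to 17880183 counts, and 14465 to 14754 genes had at least 1 read per library. Mitochondrially encoded genes took from 3.53% to 4.65% of the counts. Spearman correlations of log2 CPM lay between 0.993 and 0.997 within groups and between 0.988 and 0.992 across groups. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom within a group was 3.05. The first principal component, with 41% of the variance, separated the groups, and 1 library of each group stood apart on the next: control replicate 2 (17.9 against -9.81 and -9.03) and knockdown replicate 1 (-9.30 against 5.10 and 5.15). Knockdown replicate 1 had a chi-square per degree of freedom of 10.98 and 10.37 with the others of its group, where knockdown replicates 2 and 3 had the 3.05.

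ALKBH3 itself, ENSG00000166199 on the plus strand of chromosome 11 from 43902361 to 43941816 (hg19), was low in every knockdown library. Its raw counts were 326, 351 and 334 in the control libraries and 95, 106 and 68 in the knockdown libraries. The level fell from 22.8 ± 0.201 CPM to 5.26 ± 0.729 CPM (SD, n = 3 each), or 0.232 of the control level, with a log2 fold change of -2.11 and an SE of 0.137 (edgeR's quasi-likelihood test, adjusted p = 1.01e-10). Its neighbours on the short arm of chromosome 11 gave no call, with 0 of 12 tested members higher or lower, 0 also when adjusted over the list alone, and a median log2 fold change of -0.05 (limma camera, adjusted p = 0.925). Of these 12, 4 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test, DESeq2 and limma-voom called 0, and 1 was lower without control replicate 1.

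In the knockdown 30 of 34 tested genes of the ATF4 and stress response list rose, while 23 of 37 hypoxia and glycolysis genes, 17 of 49 G2 and mitosis genes and 8 of 18 heat shock genes fell. As lists the last 3 lost their calls (limma camera, adjusted p = 0.408, 0.408 and 0.499 with an estimated correlation). Of 12305 tested genes, 487 were higher and 507 lower in the knockdown, together 8.08% (edgeR's quasi-likelihood test, adjusted p under 0.05), and 2730 had an unadjusted p under 0.05. Most changes were small: the median size among called genes was 0.425 on the log2 scale, and 62 genes rose and 37 fell by 2-fold or more. The groups did not overlap in 26.6% of tested genes, where chance gives 10% for 3 against 3. Without knockdown replicate 2 the calls were 312 higher and 288 lower, and without knockdown replicate 3 there were 285 lower. With library totals as the only scaling, the calls divided into 610 higher and 417 lower.

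**Figure D1:**
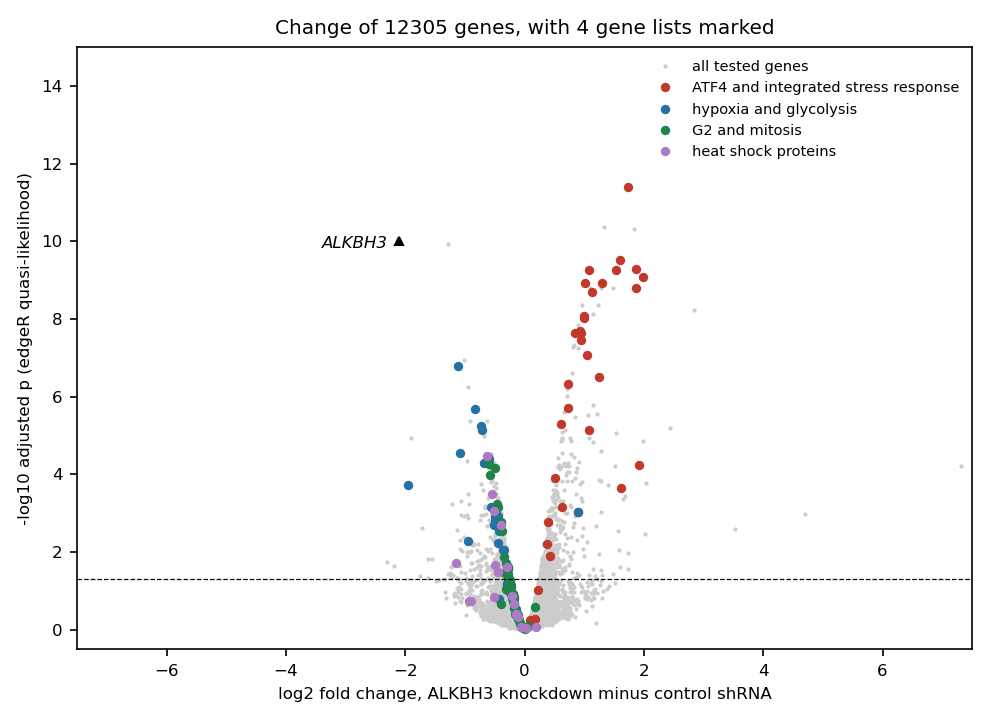
Log2 fold change (knockdown minus control, x axis) against -log10 of the edgeR adjusted p (y axis) for 12305 genes, with the threshold as a dashed line, 4 gene lists in colour and ALKBH3 as a triangle. ATF4 and integrated stress response genes lie to the right, with 30 of 34 past the threshold, and hypoxia and glycolysis genes to the left, with 23 of 37 past it.

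Among called genes with a mean of at least 5 CPM and no overlap between the groups, the highest fold changes belonged mainly to targets of ATF4, the transcription factor of the integrated stress response and of amino acid shortage. ATF4 mRNA rose from 276 ± 26.3 to 529 ± 29.6 CPM, a log2 fold change of 0.94 (edgeR's quasi-likelihood test, adjusted p = 2.34e-08). NUPR1, a stress-induced chromatin protein, rose 3.97-fold, and asparagine synthetase ASNS rose 3.77-fold, from 152 ± 38.7 to 571 ± 27.9 CPM. CTH, which makes cysteine from cystathionine, rose 3.65-fold, and the glutathione-degrading enzyme CHAC1 rose 3.63-fold, from 6.20 ± 1.39 to 22.6 ± 0.695 CPM. The serine synthesis enzyme PSAT1 rose from 158 ± 20.3 to 522 ± 30.6 CPM, with a log2 fold change of 1.73 and an SE of 0.092 (edgeR's quasi-likelihood test, adjusted p = 3.96e-12). FAM129A rose 3.58-fold, mitochondrial PCK2 3.05-fold and the pseudokinase TRIB3 3.03-fold. MT1E, a metallothionein whose reads can be confused with those of its close copies, rose from 2.52 ± 1.38 to 7.86 ± 0.849 CPM.

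Of the 34 tested members of the ATF4 and integrated stress response list, 30 rose and 0 fell, with 31 higher when adjusted over the list alone. Their median log2 fold change was 0.97 (limma camera, adjusted p = 9.84e-62). This was the 1 list call that held with an estimated correlation, at an adjusted p = 0.0336 with an estimated correlation. ATF3, PSPH, VLDLR and CEBPB, named after their values were seen, were the tested members that did not pass. The list's mean log2 level, set to 0 in the controls, was 0.966 to 1.03 in the knockdown libraries and -0.0819 to 0.0664 in the control libraries. The stress-induced genes SESN2 and GDF15 rose by 1.24 and 1.08 on the log2 scale.

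**Figure D2:**
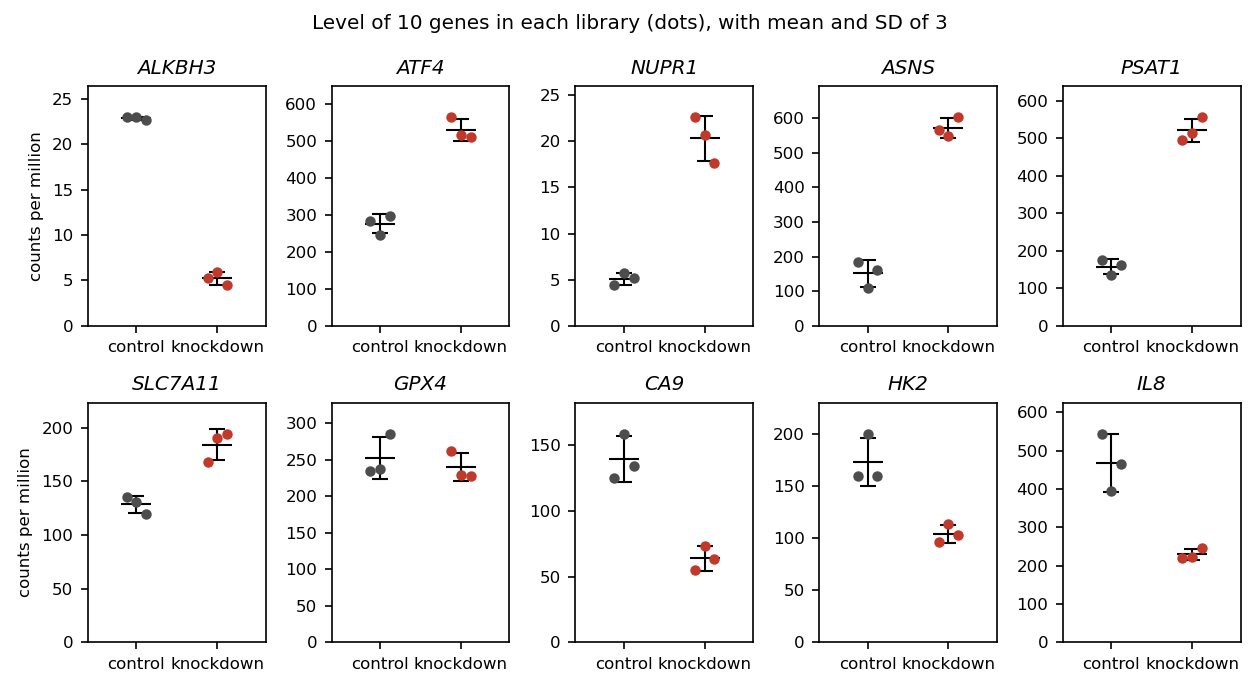
Level in CPM (y axis, from 0) of 10 genes in each library, with control shRNA in grey and ALKBH3 knockdown in red; long bars are means and error bars the SD of 3 libraries. The knockdown libraries lie apart from the controls for each gene shown except GPX4 (253 ± 28.5 against 240 ± 19.2 CPM).

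The genes by which cells import cystine and make glutathione moved in part. SLC7A11, the cystine transporter that erastin blocks, rose from 129 ± 8.07 to 184 ± 14.5 CPM, a log2 fold change of 0.52 with an SE of 0.0811 (edgeR's quasi-likelihood test, adjusted p = 1.25e-04). Its partner chain SLC3A2 rose from 169 ± 9.98 to 279 ± 11.6 CPM. CBS, the enzyme before CTH in cysteine synthesis, rose 2.29-fold, and GCLC, the catalytic subunit of the limiting enzyme of glutathione synthesis, rose 1.39-fold. Of 27 tested members of the cystine and glutathione list, 6 rose (SLC7A11, SLC3A2, GCLC, CHAC1, CTH and CBS) and 3 fell. The last were GPX1, GPX3 and GLRX, named after their values were seen, with log2 fold changes of -0.37, -0.38 and -0.42. With p adjusted over the list alone, 6 were higher and 5 lower. The list did not pass as a whole (limma camera, adjusted p = 0.0793), although it did without control replicate 3 (0.0263) and without knockdown replicate 1 (0.0381). Of the 6 that rose, 4 are also in the ATF4 list.

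GPX4, ACSL4, AIFM2 and HMOX1 did not pass the test, while some other regulators of ferroptosis moved. GPX4, which reduces lipid hydroperoxides, was at 253 ± 28.5 CPM in controls and 240 ± 19.2 CPM in the knockdown, with a log2 fold change of -0.08 (edgeR's quasi-likelihood test, adjusted p = 0.671), or 0.02 without control replicate 3. ACSL4, which loads membranes with polyunsaturated fatty acids, had a log2 fold change of 0.08 (edgeR's quasi-likelihood test, adjusted p = 0.645). The coenzyme Q reductase AIFM2 had 0.13 and the haem oxygenase HMOX1 0.18 (edgeR's quasi-likelihood test, adjusted p = 0.528 and 0.310). The transferrin receptor TFRC was lower, at 699 ± 30.8 against 573 ± 21.4 CPM with a log2 fold change of -0.29 (edgeR's quasi-likelihood test, adjusted p = 0.0274). That call was lost without control replicate 1 (0.0701), control replicate 2 (0.0551), knockdown replicate 2 (0.168) or knockdown replicate 3 (0.073). Among 25 tested ferroptosis suppressors, 2 rose (SLC7A11 and SLC3A2) and 2 fell (HSPB1 and HSPA5), against 4 and 3 when adjusted over the list alone (limma camera, adjusted p = 0.751). The 2 lower members became 1 without control replicate 2, knockdown replicate 2 or knockdown replicate 3, and the 2 higher became 4 without knockdown replicate 1, with library totals as the only scaling or with DESeq2. Among 31 tested drivers, 4 rose, among them CHAC1 (3.63-fold) and the amino acid transporters SLC1A5 (1.87-fold) and SLC38A1 (1.76-fold), and TFRC fell, the same counts as when adjusted over the list alone (limma camera, adjusted p = 0.237, or 0.0416 without knockdown replicate 1).

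The lists of iron handling and of NRF2 targets did not pass. Of 24 tested iron genes, 0 rose and 1 fell (TFRC), also when adjusted over the list alone (limma camera, adjusted p = 0.974). Of 31 tested NRF2 targets, 2 rose (SLC7A11 and GCLC) and 2 fell (UGDH and, named after its value was seen, AKR1C1), against 5 and 4 when adjusted over the list alone (limma camera, adjusted p = 0.596). UGDH lost its call without knockdown replicate 1 (0.0586) or knockdown replicate 2 (0.0522). The lower NRF2 targets numbered 4 without control replicate 1, 0 without knockdown replicate 1 and 1 without knockdown replicate 2, and the higher ones 4 without knockdown replicate 1. With all libraries kept, the higher NRF2 targets numbered 5 with library totals as the only scaling or with DESeq2 and 4 with limma-voom, and DESeq2 called 2 lower iron genes.

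Most tested genes of hypoxia and glycolysis fell. The hypoxia-induced carbonic anhydrase CA9 fell from 139 ± 17.3 to 63.8 ± 9.25 CPM, a log2 fold change of -1.12 (edgeR's quasi-likelihood test, adjusted p = 1.59e-07). EGLN3, an oxygen-sensing prolyl hydroxylase, fell from 24.8 ± 6.17 to 11.8 ± 0.804 CPM. Hexokinase HK2 fell from 173 ± 23.3 to 104 ± 8.52 CPM, and PFKFB4, which makes the activator of phosphofructokinase, from 52.4 ± 6.63 to 29.3 ± 0.553 CPM. Of 37 tested members of the hypoxia and glycolysis list, 23 fell and 1 rose, against 31 and 1 when adjusted over the list alone. The member that rose, DDIT4, was named after its value was seen and is also in the ATF4 list. The list's median log2 fold change was -0.43 (limma camera, adjusted p = 3.36e-24), a call lost at an adjusted p = 0.408 with an estimated correlation. Its mean log2 level was -0.544, -0.363 and -0.404 in the knockdown libraries, against -0.124, 0.151 and -0.0272 in the controls.

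Some genes of the cell cycle fell. CDC20, an activator of the anaphase-promoting complex, fell from 337 ± 31.2 to 222 ± 23.2 CPM, the mitotic kinesin KIF20A from 288 ± 10.4 to 203 ± 2.02 CPM, and the condensin subunit NCAPH from 65.6 ± 5.23 to 44.0 ± 2.20 CPM. Of 49 tested genes of G2 and mitosis, 17 fell and 0 rose, with 31 lower when adjusted over the list alone, and the median log2 fold change was -0.23 (limma camera, adjusted p = 9.49e-16; adjusted p = 0.408 with an estimated correlation). The count was 8 without knockdown replicate 2 and 11 without knockdown replicate 3. Among genes of DNA replication and S phase, the replication factors GINS4, CDC6 and GINS1 fell by 0.57, 0.49 and 0.38 on the log2 scale. Here 9 of 45 tested members fell and 0 rose, with 12 lower when adjusted over the list alone (limma camera, adjusted p = 2.43e-08; adjusted p = 0.784 with an estimated correlation). The 9 became 16 without control replicate 2 and 4 without knockdown replicate 2. The groups overlapped in this list's mean log2 level. The controls were at 0.0715, -0.112 and 0.0403 and the knockdown libraries at -0.104, -0.239 and -0.209, so control replicate 2 lay below knockdown replicate 1.

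Several heat shock proteins fell. HSP90AA1, the inducible cytosolic HSP90, fell by 0.55 on the log2 scale, to 3827 ± 178 CPM, the small heat shock protein HSPB1 from 603 ± 72.5 to 389 ± 19.3 CPM, and the co-chaperone DNAJB1 from 729 ± 106 to 509 ± 36.9 CPM. HSPA6, which has a near-identical copy, had a log2 fold change of -1.15 (edgeR's quasi-likelihood test, adjusted p = 0.0195). It lost its call without control replicate 3 (0.0827) and without knockdown replicate 1 (0.0579), 2 (0.0539) or 3 (0.0585). Of 18 tested members, 8 fell and 0 rose, with 10 lower when adjusted over the list alone, and the median log2 fold change was -0.42 (limma camera, adjusted p = 1.29e-10; adjusted p = 0.499 with an estimated correlation). The count was 4 without knockdown replicate 1, 5 without knockdown replicate 2 and 4 without knockdown replicate 3. Control replicate 2 stood above the other controls in the list's mean log2 level, at 0.287 against -0.170 and -0.117, and the knockdown libraries were at -0.454, -0.336 and -0.363.

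Chaperones of the endoplasmic reticulum did not follow the ATF4 genes upward. HSPA5, the main chaperone of that compartment, was lower, at 1967 ± 270.0 against 1521 ± 27.9 CPM (edgeR's quasi-likelihood test, adjusted p = 0.0143), and PDIA4 had a log2 fold change of -0.29 (edgeR's quasi-likelihood test, adjusted p = 0.0307). The HSPA5 call was lost without control replicate 2 (0.0887), knockdown replicate 2 (0.0678) or knockdown replicate 3 (0.073). That of PDIA4 was lost without control replicate 2 (0.111) and without knockdown replicate 1 (0.0584), 2 (0.109) or 3 (0.122). Of 20 tested members, 4 fell (HSPA5, PDIA4, and SDF2L1 and MANF, named after their values were seen) and the transcription factor XBP1 rose by 0.33 on the log2 scale, against 8 lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.16 (limma camera, adjusted p = 0.00243; adjusted p = 0.83 with an estimated correlation). Without control replicate 2, which had the highest mean log2 level of the list (0.145 against -0.0854 and -0.0601), the list did not pass (0.212), 0 members were lower and 2 higher. The lower members numbered 1 without knockdown replicate 1, and 0 without knockdown replicate 2 or 3, and 2 with library totals as the only scaling.

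**Figure D3:**
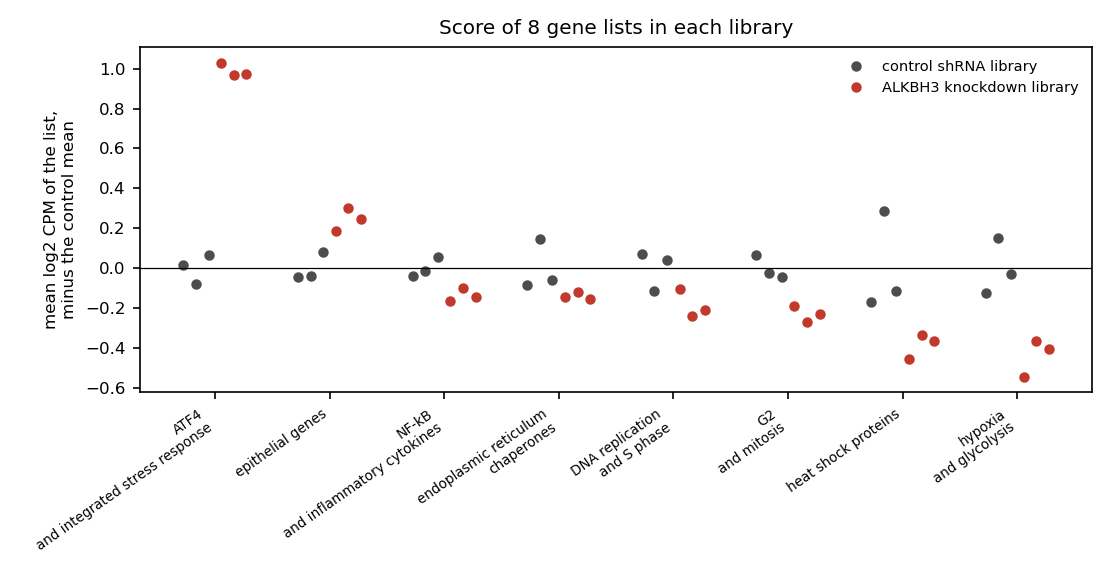
Mean log2 CPM of the tested members of 8 gene lists in each library, minus the mean of the control libraries (y axis), with control shRNA in grey and ALKBH3 knockdown in red. The ATF4 list lies at 0.966 to 1.03 in the knockdown libraries. Control replicate 2 is the highest control for heat shock proteins (0.287) and for hypoxia and glycolysis (0.151). For DNA replication and S phase the groups overlap, with control replicate 2 at -0.112 and knockdown replicate 1 at -0.104.

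Inflammatory cytokine genes moved in both directions, with more of them lower. IL8, a neutrophil chemokine, fell from 467 ± 75.0 to 230 ± 14 CPM, a log2 fold change of -1.02 (edgeR's quasi-likelihood test, adjusted p = 1.14e-07). PTGS2, the inducible cyclooxygenase, fell by 0.82 and IL32 by 0.59 on the log2 scale. The cytokine IL24 fell from 15.1 ± 4.96 to 4.01 ± 0.481 CPM and the bradykinin receptor BDKRB1 from 6.88 ± 0.562 to 3.28 ± 0.400 CPM. CCL2 and IL1A, named after their values were seen, rose by 1.28 and 0.86 on the log2 scale. Of 24 tested members of the NF-kB list, 6 fell and 2 rose, against 9 and 2 when adjusted over the list alone (limma camera, adjusted p = 0.0124; adjusted p = 0.489 with an estimated correlation). In the type I interferon list, 6 of 36 tested members rose and 1 fell, against 9 and 1 when adjusted over the list alone (limma camera, adjusted p = 0.169). XAF1 rose 2.09-fold and the transcription factor IRF1 1.54-fold. The 6 became 2 without control replicate 1, 3 without control replicate 3, and 2 without knockdown replicate 2 or 3, and the 1 became 2 without control replicate 1 and 0 without control replicate 2 or 3 or knockdown replicate 1 or 3. Of 19 tested antigen presentation genes, 0 passed in edgeR's quasi-likelihood test, also when adjusted over the list alone (limma camera, adjusted p = 0.623). In that list 6 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and 2 were higher without control replicate 3 and 1 lower without control replicate 1.

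The line expressed few epithelial genes, and several of those measured rose. CDH1, the epithelial cadherin, had 0 reads in all 6 libraries and EPCAM 54 in total, while the mesenchymal filament VIM was at 3840 ± 168 and 3860 ± 44.4 CPM. Of 9 tested epithelial genes, 5 rose and 0 fell, against 5 and 1 when adjusted over the list alone. KRT7 rose from 6.88 ± 1.53 to 13.2 ± 2.04 CPM, the tight junction protein TJP1 1.31-fold and KRT18 1.30-fold; KRT8 and PKP3, named after their values were seen, rose by 0.41 and 0.46 on the log2 scale. KRT8 and KRT18 have many processed copies in the genome and are uncertain. The list passed (limma camera, adjusted p = 0.0161; adjusted p = 0.408 with an estimated correlation), but not without control replicate 2 (0.0546). Of 31 tested mesenchymal genes, 5 fell and 1 rose, against 6 and 1 when adjusted over the list alone (limma camera, adjusted p = 0.231); ITGA5 fell by 0.41 and TAGLN rose by 0.97 on the log2 scale. The 5 became 1 without control replicate 2 or knockdown replicate 1, 3 without control replicate 3, and 2 without knockdown replicate 2 or 3.

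RNA methylation enzymes other than ALKBH3 showed 1 call. Of 16 tested writers, erasers and readers of m1A, 0 rose and 1 fell, which was ALKBH3, also when adjusted over the list alone (limma camera, adjusted p = 0.316). Among 22 tested other AlkB dioxygenases and m6A enzymes, 0 rose and 1 fell, also when adjusted over the list alone (limma camera, adjusted p = 0.925). That gene, the m6A demethylase ALKBH5, fell from 137 ± 6.92 to 104 ± 9.95 CPM (edgeR's quasi-likelihood test, adjusted p = 0.00243). Of 14 tested partners of ALKBH3 and transcripts reported as its substrates, ATF4 rose and 3 fell, namely AURKA by 0.39 and ALDOA by 0.36 on the log2 scale and MMP9, named after its value was seen. When adjusted over the list alone, 1 was higher and 4 lower (limma camera, adjusted p = 0.573). Without knockdown replicate 3 the 3 became 1, and ALDOA lost its call (0.0606).

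The single genes furthest from the controls included some outside these groups. SPIN1, a reader of histone methylation, fell from 130 ± 13 to 53.4 ± 1.93 CPM, a log2 fold change of -1.29 with an SE of 0.0851 (edgeR's quasi-likelihood test, adjusted p = 1.18e-10). HIST1H2BH, a histone gene with near-identical copies, had a log2 fold change of -1.21 (edgeR's quasi-likelihood test, adjusted p = 5.94e-04). Of 17 listed replication-dependent histones, 7 had enough counts to be tested. Of these 7, 0 passed in edgeR's quasi-likelihood test, DESeq2 or limma-voom, also when adjusted over the list alone (limma camera, adjusted p = 0.925). At an unadjusted p under 0.05 in edgeR's test there were also 0. The RNA was enriched with oligo dT, so histone transcripts without a poly(A) tail are not measured by these values or by that of HIST1H2BH.

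Lists for lipid synthesis, growth and turnover moved little. No list here passed, and each count stands with its range over the 6 fits without 1 library; every library, left out alone, moved at least 1 of these counts by over 1.5 times. Cholesterol synthesis had 1 of 24 higher (0 to 3) and 3 lower (1 to 3), against 3 and 3 when adjusted over the list alone (limma camera, adjusted p = 0.904). Fatty acid synthesis had 2 of 24 higher (1 to 4) and 1 lower (0 to 1), against 3 and 1 adjusted over the list alone (limma camera, adjusted p = 0.499). DNA repair had 1 of 52 higher (0 to 2) and 2 lower (1 to 4), against 0 and 2 adjusted over the list alone (limma camera, adjusted p = 0.517); RAD54L fell by 0.41. Apoptosis and BCL2 family genes had 4 of 29 higher (2 to 4) and 1 lower (1 in each fit), against 5 and 1 adjusted over the list alone (limma camera, adjusted p = 0.85), with the survival gene BCL2L1 and the pro-apoptotic gene PMAIP1 up by 0.40 and 0.38. Autophagy and lysosome genes had 3 of 40 higher (0 to 3) and 0 lower (0 in each fit), as also when adjusted over the list alone (limma camera, adjusted p = 0.925). Ribosome biogenesis and MYC targets had 0 of 39 higher (0 in each fit) and 1 lower (0 to 1), the same adjusted over the list alone (limma camera, adjusted p = 0.925). Of 56 nuclear respiratory chain genes (limma camera, adjusted p = 0.925), 13 mitochondrially encoded genes (0.952) and 74 cytosolic ribosomal proteins (0.751), 0 passed in edgeR's quasi-likelihood test, DESeq2 or limma-voom, also when adjusted over the list alone. At an unadjusted p under 0.05 they had 1, 0 and 2 members, and without control replicate 1 they had 2, 1 and 4 lower members.

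**Figure D4:**
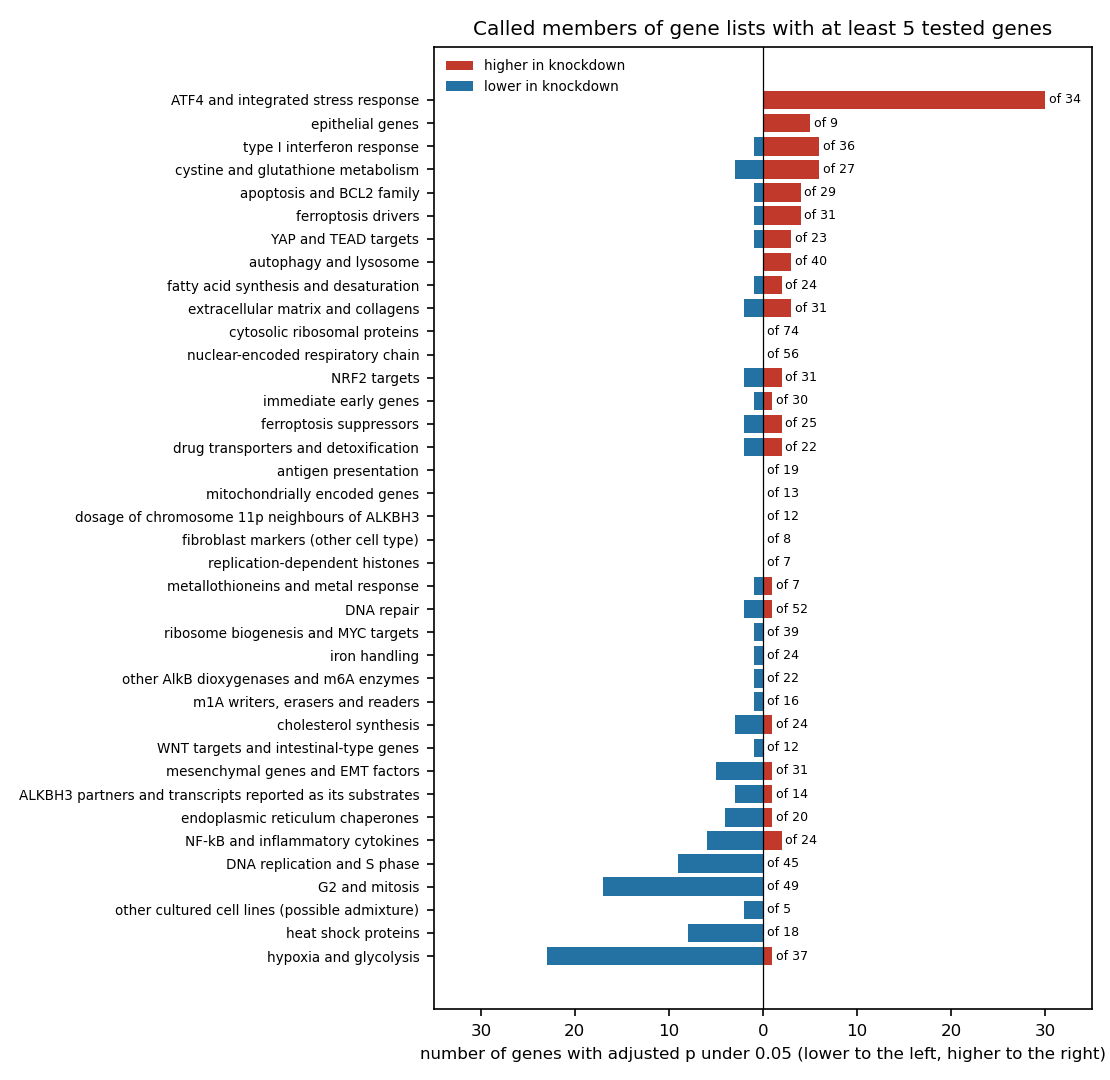
Number of members with an edgeR adjusted p under 0.05 in each list shown, all of at least 5 tested genes (x axis, lower in blue to the left, higher in red to the right), with the number tested beside each bar. The longest bars are ATF4 and integrated stress response (30 of 34 higher), hypoxia and glycolysis (23 of 37 lower) and G2 and mitosis (17 of 49 lower).

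Signalling and matrix lists also did not pass, and their ranges over the 6 fits without 1 library follow each count; every library, left out alone, moved at least 1 of them by over 1.5 times. Immediate early genes had 1 of 30 higher (1 to 2) and 1 lower (1 to 4), the same adjusted over the list alone (limma camera, adjusted p = 0.85): KLF4 rose 1.85-fold and FOSL2 fell by 0.41 on the log2 scale. YAP and TEAD targets had 3 of 23 higher (2 to 3) and 1 lower (1 in each fit), as when adjusted over the list alone (limma camera, adjusted p = 0.237), with AJUBA and ANKRD1 up by 0.63 and 0.68 and tissue factor, F3, at -0.48. Extracellular matrix genes had 3 of 31 higher (1 to 3) and 2 lower (1 to 2), against 3 and 4 adjusted over the list alone (limma camera, adjusted p = 0.925), among them EFEMP1 at 0.38 and NID2 at -0.39, with 4 lower when no filter on low counts was used. WNT targets and intestinal-type genes had 0 of 12 higher (0 to 1) and 1 lower (0 to 1), the same adjusted over the list alone (limma camera, adjusted p = 0.352). Drug transporters and detoxification genes had 2 of 22 higher (2 to 3) and 2 lower (1 to 2), against 3 and 2 adjusted over the list alone (limma camera, adjusted p = 0.623), and the aldehyde dehydrogenases ALDH1A3 and ALDH3A2 were the higher ones, by 0.44 and 0.35. Metallothioneins and metal response genes had 1 of 7 higher (1 to 2), MT1E, and 1 lower (0 to 1), SLC30A10, against 2 and 2 adjusted over the list alone (limma camera, adjusted p = 0.623). Of 4 tested gastric epithelial genes, 0 passed in edgeR's quasi-likelihood test, DESeq2 or limma-voom, also when adjusted over the list alone (limma camera, adjusted p = 0.974), and 1 had an unadjusted p under 0.05. The gastric and intestinal markers CLDN18 and CDX2 had 0 reads in all 6 libraries.

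Other called members of these lists included ACAT2, HMGCS1, INSIG1, ACSL3, SREBF1, SCD5, XPC, NEIL3, ULK1, MAP1LC3B, GABARAPL1, SRM, BMF, XIAP, BIRC3, AMOTL2, LAMB1, COL18A1, NID1, TCF7, CYP24A1 and AKR1C1, and in the mesenchymal and interferon lists LOX, SPARC, TGFBI, MMP9, IFIT3, DDX60, SAMD9L, DTX3L and IFI6. INSIG1, BMF, XIAP, AMOTL2, COL18A1, NID1, AKR1C1, SPARC, TGFBI, MMP9, IFIT3, SAMD9L, DTX3L and IFI6 are named after their values were seen. The calls of these 14 genes without single libraries were not examined. Among the genes named by the rule, leaving out 1 library ended the calls of ACAT2, HMGCS1, ACSL3, SREBF1, SCD5, XPC, NEIL3, ULK1, MAP1LC3B, GABARAPL1, SRM, LAMB1, TCF7, CYP24A1, LOX and DDX60, and of SLC30A10 in the metallothionein list. Their adjusted p in edgeR's quasi-likelihood test then ran from 0.0507 (MAP1LC3B without control replicate 2) to 0.201 (XPC without knockdown replicate 1), and each of the 6 libraries ended at least 1 of these calls.

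Markers of other cell types gave no list call. Of 8 tested fibroblast markers 0 passed in edgeR's quasi-likelihood test, against 1 higher and 2 lower when adjusted over the list alone (limma camera, adjusted p = 0.409). Of the 8, 4 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1 lower. The line itself expressed several of them, with COL1A2 at 2250 ± 213 and 2080 ± 185 CPM and THY1 at 651 ± 46.2 and 577 ± 28.3 CPM, while DCN had 11 reads in total and LUM 10. Without control replicate 2, 1 fibroblast marker was higher, and without knockdown replicate 1, 1 was lower. The leukocyte and endothelial lists each had 1 tested gene and 0 calls by edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05, also when adjusted over the list alone (limma camera, adjusted p = 0.974 and 0.832). Of 5 tested markers of other cultured lines, 2 were lower (ESR1 and PAX8), also when adjusted over the list alone (limma camera, adjusted p = 0.703). Those 2 became 1 without any 1 control library or without knockdown replicate 2, and 0 without knockdown replicate 1 or 3, and DESeq2 called neither (adjusted p = 0.113 for ESR1 and 0.0573 for PAX8). Median and mean log2 fold change had opposite signs in the lists of iron handling, other AlkB and m6A enzymes, mitochondrially encoded genes, apoptosis, autophagy, drug transporters, metallothioneins and histones, which did not pass.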

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

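The settings were planned before the data were examined. ALKBH3 kept its direction and its call under all 15 alternatives, with log2 fold changes from -2.019 to -2.213. Higher genes numbered 251 and lower genes 207 at an adjusted p under 0.01, and 62 and 37 with a fold limit of 2. Leaving out 1 library gave 312 to 433 higher and 285 to 423 lower genes; fewer samples enter these fits. Of the 88 called named genes beside ALKBH3, 63 kept sign and call under all alternatives and 82 under those with all libraries, and 0 reversed; the cause of the lost calls was not tested. GPX4, not called, changed sign without control replicate 3 (log2 fold change 0.02148, the highest of the 6 such fits, the lowest being -0.144). Camera with an estimated correlation passed 1 list instead of 8, and fry in either direction passed 35. Fry for 1 direction passed 6, without hypoxia and glycolysis (0.0544), heat shock (0.157), S phase (0.217) or endoplasmic reticulum chaperones (0.329), but with cystine and glutathione metabolism (0.0288) and the m1A list, which holds ALKBH3 (0.0346). Lists past the threshold numbered 6 to 11 when 1 library was left out. For the lists, 1101 counts of members stayed within 1.5 times of the reported count and 159 did not. At 14244932 to 17880183 counts a library, changes of weakly expressed genes below about 1.5-fold can be missed. The simulation recovered 85% of genes planted at 1.5-fold. Its single genes were drawn without regard to level and planted at 1.5-fold or 2-fold. It therefore did not measure the recovery of smaller changes or of weakly expressed genes alone.

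With the replicate number as a replicate block, 587 genes were higher and 647 lower, including the 487 and 507 of the fit without it. The numbers were not taken as pairs because nothing in the labels says that they mark a shared culture or day, a choice made in advance. Same-numbered libraries deviated together with correlations of 0.0579, 0.107 and -0.0556, and 3 of 6 libraries correlated best with their own number. With so few libraries these values cannot exclude a pairing. The block passed 9 lists, the 8 and cystine and glutathione metabolism (limma camera, adjusted p = 0.0203).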

Other observations

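The term enrichments, the comparison of synthetases and the tests of GC content and length, of the unfolded protein response, of culture differences and of hairpin seeds were chosen only after the results were seen; the splits of the libraries and the thinning to equal depth were planned before.

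Of 20 tested aminoacyl-tRNA synthetases of the cytosol, any shared with mitochondria included, 11 rose and 1 fell, with a median log2 fold change of 0.60. The 11 were AARS, CARS, EPRS, GARS, IARS, MARS, NARS, SARS, TARS, WARS and YARS. Of 17 counted as mitochondrial only, 0 rose and 1 fell, with a median of -0.01. The higher share differed (Fisher's exact test, two-sided, p = 0.000211), with genes not independent of each other and the contrast resting on that assignment. Of the 11, 5 are also in the ATF4 list. Among annotation terms, amino acid transport held 9 higher genes of 19 where 0.75 were expected (hypergeometric test, adjusted p = 6.29e-06), among them SLC1A4 at a log2 fold change of 1.48 and SLC7A1 at 0.47. INHBE, a secreted activin subunit, rose from 0.990 ± 0.187 to 7.17 ± 0.570 CPM, a log2 fold change of 2.84 (edgeR's quasi-likelihood test, adjusted p = 5.75e-09). SPNS3, a transporter of the spinster family on chromosome 17 from 4336983 to 4391503 (hg19), had 0 reads in each control library and 30, 22 and 12 in the knockdown libraries, at least 6.07-fold higher against a floor of 3 counts per library (edgeR's quasi-likelihood test, adjusted p = 6.18e-05). The floor covers counting error only. TNFSF18 had 0, 1 and 0 reads in the control libraries and 15, 14 and 11 in the knockdown libraries, and SLC6A4 1, 2 and 0 against 15, 19 and 10 (edgeR's quasi-likelihood test, adjusted p = 0.00106 and 0.00251).

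Among lower genes 12 biological process terms and 3 pathways passed, against 4 and 3 among higher genes. The hypergeometric test takes genes as independent of each other, so its p-values may be too small for co-regulated genes. The lists of G2 and mitosis and of hypoxia and glycolysis share genes with the leading lower terms. Both lost their calls with an estimated correlation (limma camera, adjusted p = 0.408 for each). The lower terms were led by mitotic cell cycle, with 38 of 284 genes (hypergeometric test, adjusted p = 1.59e-07). Glycolysis followed with 11 of 29 (hypergeometric test, adjusted p = 6.29e-06). Further down was glycosaminoglycan biosynthesis, with 7 of 26 genes where 1.07 were expected (hypergeometric test, adjusted p = 0.00962). The 7 include the cell surface proteoglycans SDC1 and SDC4, with log2 fold changes of -0.29 and -0.34. The term for hexose transport passed with 8 of 29 genes (hypergeometric test, adjusted p = 0.00311), but 5 of the 8 were nucleoporins (NUP85, NUP93, NUP155, NUP188 and NUP205, from -0.27 to -0.39). These also make up much of mitotic nuclear envelope disassembly, with 7 of 28 genes lower (hypergeometric test, adjusted p = 0.0138). The annotated ferroptosis pathway had 7 of 33 genes higher where 1.5 were expected and missed the threshold (hypergeometric test, adjusted p = 0.0522). SPIN1 fell, while its relatives SPIN3 and SPIN4 had log2 fold changes of 0.10 and -0.15 (edgeR's quasi-likelihood test, adjusted p = 0.777 and 0.485). Transcripts of the eIF2alpha kinases EIF2AK1, EIF2AK2, EIF2AK3 and EIF2AK4, of HIF1A and of HSF1 did not pass (edgeR's quasi-likelihood test, adjusted p = 0.506, 0.946, 0.927, 0.672, 0.772 and 0.116). Apart from SPIN1, the single genes in this paragraph and the one before were chosen after their values were seen.

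The 6 libraries can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 994 called genes, 487 higher and 507 lower, and 1 of the 10 divisions, the real one, gave as many in total and in each direction; the highest other gave 0. Each of the other divisions still parts the groups 2 to 1. For gene lists past the threshold, 7 of the 10 divisions gave as many as the real one, with 8 lists in the real division and 16 in the highest other. Ribosomal and respiratory chain lists passed in 6 of the other divisions, with adjusted p down to 3.78e-17 and 4.8e-10 (limma camera). The preset correlation of 0.01 lies below the 0.58 and 0.34 estimated for these lists. Such p-values can therefore be too small, as can those of other lists of correlated genes. A structure of the libraries apart from the hairpin cannot be told apart from this. The ATF4 list passed in 9 of the other divisions, the hypoxia list and G2 and mitosis in 7 each, and heat shock proteins in 6. Passing was therefore not particular to the real division for these lists. The smallest adjusted p of the ATF4 list in another division was 2.2e-10 against 9.84e-62, and of the hypoxia list 2.03e-15 against 3.36e-24 (limma camera). The real division did not give the smallest value for DNA replication and S phase (3e-16 in another division against 2.43e-08) or for endoplasmic reticulum chaperones (3.87e-04 against 0.00243, limma camera), and for the chaperones 4 of the 10 divisions gave a value as small.

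The rise of the ATF4 and integrated stress response genes was weighed first. The trend with GC content and length over 12079 genes was small, with an SD of 0.021 on the log2 scale, so its removal could move few lists. The size of the trend argues against it as the cause: at the list's genes it ran from -0.0276 to 0.0718, against a median log2 fold change of 0.971, or 0.989 with the trend removed (quartiles 0.609 and 1.27). With all libraries thinned to the smallest total the median was 0.964. Thinning keeps the expected scaled fold change of each gene, so this value cannot decide on a difference in depth. A general unfolded protein response of the endoplasmic reticulum would raise the chaperone list, whose median log2 fold change was -0.159; XBP1 rose, however, and without control replicate 2 that list no longer passed (0.212). A candidate explanation that stays open, and was not tested, is activation of ATF4 by another arm, such as amino acid shortage in the knockdown cells, which could be followed by measuring eIF2alpha phosphorylation and intracellular amino acids. An effect of the hairpin apart from ALKBH3 also stays open.

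For the fall of the hypoxia and glycolysis genes, the trend with GC content and length ran from -0.0289 to 0.045 at the list's genes, against a median log2 fold change of -0.431, or -0.415 with the trend removed. The size of the trend argues against it as the whole cause. With depth made equal the median was -0.424, with 23 members lower. Thinning keeps the expected scaled fold change, so no conclusion about depth is drawn from it. Culture density or oxygen differing between the arms may lower the same genes. The largest range of the list's mean log2 level within 1 arm was 0.275, against a gap of 0.24 between the nearest libraries of the arms, but each arm's culture and its hairpin coincide, so the effects cannot be told apart here. Lactate and oxygen measured in parallel cultures of matched density could help to tell them apart, although either effect might change both.

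An off-target effect of the hairpin through matches of its seed in 3' UTRs could lower many genes. The hairpin sequence is not given in the sources used here, so all 1358 7-mers of the ALKBH3 transcript that passed the scan's minimum were tried over 10121 genes. The largest excess of any of them among the 452 lower genes scanned was 5.09 percentage points, where random draws of as many genes gave a median of 4.97 and a 95th percentile of 6.13. No 7-mer shifted the fold changes past an adjusted p of 0.05 (0 of 16126), and the most negative among those of ALKBH3 was -0.042 with an SE of 0.012. These values argue against seed matches as the main cause of the lower genes, while direct off-targets on single genes were not tested and stay open.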
